A study of Homo sapiens with 8 samples.

How the data were processed

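The data were 8 microarrays of the colorectal adenocarcinoma lines COLO205 and SNU-C1, each treated for 24 hours with 0.1% or 5% of 1 of 2 cell-free ascites fluids. Per the labels' protocols, total RNA was extracted with a column kit and labelled with biotin. The protocol text names the Affymetrix U133 Plus 2.0 array, while the identifiers of the value table and the platform annotation are those of the Human Gene 2.0 ST array, and the latter was used for gene names. The values were taken from the deposited series table, which holds the authors' processed values for 53617 probe rows and 8 arrays. The deposited values were read as log2 intensities, from their range of 0.738 to 13.6 and per-array medians of 4.27 to 4.32. The log base is not stated and was taken as 2, so that every log2 difference rests on that reading. Per the submitters' processing notes R 3.4.2 was used. The background correction, normalization and summarisation of probes are not given in the sources used here, and no detection calls were used, so that a low signal cannot be told apart from background. Columns that match no sample numbered 0.

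Arrays were grouped by line and dose from their titles. The ascites fluid is the replicate of each group, and arrays with the same fluid were treated as paired because the labels give them the same source fluid. As a check, the deviations of arrays with the same fluid from their group means correlated at 0.0181 to 0.158 across genes. No values were identical between replicates. A gene symbol was given to 16098 probe rows, each with 1 symbol, while no row had several and 37519 rows are unnamed here. All 16098 were matched by Entrez identifier to the GRCh38.p14 gene table for current symbols. No coordinates were used. For the 779 of 14884 genes with several probe rows, the row with the highest mean over all arrays was kept. Genes whose mean lay above the 30th percentile of all gene means (4.32 on the log2 scale) were tested, which left 10419.

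Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) to all 8 arrays, with the 4 groups and a term for the fluid. This left 3 residual degrees of freedom, to which the moderated variance added 5.35, and the median moderated residual SD was 0.0928 log2 units. The contrasts were the dose effect averaged over the lines, the dose effect in each line, its difference between lines, the difference between lines and the difference between fluids. A term for the dose by fluid was added after the data had been seen. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over 10419 genes for each contrast, with a threshold of 0.05. The genes named were those 12 with the largest rise and 12 with the largest fall past the threshold with the same sign in every pair of arrays, or 5 in each direction for differences of effects. To these were added up to 4 members of a list with the smallest p in its direction, and 13 genes fixed for the dose effect. Of the latter 8 were tested, and the others are not analysed here. MYC within its target list and the genes of the added list of growth arrest were chosen after their values were seen. Of 106 named calls 14 rest on genes with several probe rows, and every other row of these genes had the same sign.

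Before the data were examined 42 lists of genes of pathways, cell states and other cell types were written, with 1010 genes, of which 605 are named here and 512 passed the filter. The 36 lists with at least 5 tested genes were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. Camera compares a list with the other genes, whereas fry asks whether its genes move on balance in 1 direction. Adjustment of list p-values was over the 36 lists of a contrast.

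The procedure was tested on simulated data for the 10419 genes, in which 67 genes each were changed by 0.3, 0.5 and 1 log2 unit. The simulated noise was normal, independent between genes and without a fluid effect, and far fewer genes changed than passed in the real data. The shares recovered describe these settings and may not hold for the real arrays. For the dose effect averaged over the lines 74.6%, 98.5% and 100% of them were recovered, with 15 unchanged genes called. For the dose effect in COLO205 the shares were 13.4%, 92.5% and 100%, with 13 unchanged genes called. For the difference of the dose effect between lines they were 1.49%, 16.4% and 97.0%, with 13 unchanged genes called.

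Alternatives were a fit without the fluid term, a block for each line and fluid pair, an additive model, an intensity trend or robust settings in the variance prior, no filter or one at the 50th percentile, other handling of several probe rows, another scaling of the arrays, single fluids or lines, an adjusted p of 0.1 and the omission of each array in turn. The median dose effect of all genes lay within 0.0415 log2 units of 0 in every setting, and 3 of 59 list calls in 6 contrasts were lost under another scaling, those of metallothioneins between fluids (adjusted p = 0.0625), of ribosomal proteins for the difference of dose effects (0.0599) and of the IL6-STAT3 response in SNU-C1 (0.0521). Rows without a name were left out of the gene counts. Differences between groups were taken within the probe rows of a gene. Levels of different probes were compared to filter genes, choose probe rows, match random lists and describe markers of cell types. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.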

Results

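Gene expression was measured on microarrays in COLO205 and SNU-C1, established lines of human colorectal adenocarcinoma, after 24 hours with cell-free ascites. Ascites is fluid that collects in the abdominal cavity, and per the labels it was taken here from peritoneal carcinomatosis of colorectal origin, the spread of such tumours over the lining of that cavity. Each line was given 0.1% or 5% of each of 2 ascites fluids, with 1 array for each combination. This makes 4 groups of 2 arrays (COLO205 at 0.1%, COLO205 at 5%, SNU-C1 at 0.1%, SNU-C1 at 5%) in which the replicates are the fluids. No array of untreated cells was analysed here, so every dose effect is the value at 5% minus the value at 0.1% of the same fluid. The per-array median signal lay between 4.27 and 4.32 on the log2 scale, and the number of arrays limits the precision. Arrays of the same line and dose with the other fluid correlated at 0.992 to 0.995 across 10419 genes, arrays of the same line and fluid at the other dose at 0.980 to 0.990, and arrays of different lines at 0.869 to 0.888. Changes are log2 differences with their standard errors, and p-values are limma's after Benjamini-Hochberg adjustment. They measure the spread between cultures given these 2 fluids. In averages over both lines, neither the p-values nor the standard errors include the spread between the lines. A signal under the filter level of 4.32 was not shown to be above background, so a change from or to such a signal is a lower bound.

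The dose comparison averaged over both lines asks which transcripts changed with more ascites on average over the lines. The extracellular matrix glycoprotein tenascin C (TNC) rose by 1.56 ± 0.12 on the log2 scale, or 2.95-fold, from 0.1% to 5% ascites (n = 4 pairs of arrays, adjusted p = 0.000446). This average describes neither line, as the rise was 3.03 and 2.18 in COLO205 and 0.46 and 0.58 in SNU-C1 with fluids 1 and 2. The microRNA gene MIR4521 rose by 1.57 ± 0.10 (adjusted p = 0.000446). CD38, an enzyme on the cell surface that consumes NAD, fell by 1.47 ± 0.06 (adjusted p = 6.0e-05), a fall seen in SNU-C1, as its signal in COLO205 lay under the filter level, and the methyltransferase gene TMT1A, formerly METTL7A, fell by 1.47 ± 0.12 (adjusted p = 0.000446). With camera, lists of G2 and mitosis (23 of 31 genes higher), S phase (23 of 29) and MYC targets (15 of 23) rose, while cholesterol synthesis (13 of 19 lower) and Wnt targets (14 of 19) fell. None of these lists passed with an estimated correlation between genes, where the adjusted p was 0.322 for Wnt targets and 0.575 for the others.

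Among 10419 genes tested, 2534 passed an adjusted p of 0.05 for the dose averaged over both lines, 1139 higher and 1395 lower at 5%. More rose than fell when arrays were quantile normalized again (1350 and 1269) or centred on their median (1346 and 1279). Of the 2534 genes, 2205 had the same sign in all 4 line and fluid pairs. Most changes were small, since 19 genes passed and moved at least 2-fold, 10 up and 9 down. The other large rises included small proline-rich proteins of the cornified envelope, SPRR1B at 1.57 ± 0.34, SPRR3 at 1.18 ± 0.15 and SPRR1A at 0.95 ± 0.22. The cell adhesion molecule CEACAM6 rose by 1.47 ± 0.36. This size rests on COLO205 with fluid 1 (3.38, against 0.73 to 0.90 in the other pairs), as does that of SPRR1B (3.30, against 0.62 to 1.61). GPAT3, an acyltransferase of triacylglycerol synthesis, rose by 0.95 ± 0.14, and the heme-degrading enzyme HMOX1 by 0.92 ± 0.20. The metallothionein MT2A rose by 0.94 ± 0.25, but in SNU-C1 by 1.73 with fluid 1 and 0.18 with fluid 2. HMOX1 rose more with fluid 1 (1.29 in COLO205 and 1.64 in SNU-C1) than with fluid 2 (0.21 and 0.53). SPRR1A was at 2.01 in SNU-C1 with fluid 1, against 0.29 to 0.99 in the other pairs. Rises were also measured for the small noncoding RNA genes SNAR-B1 (1.26 ± 0.09), SNAR-C1 (1.11 ± 0.09) and SNAR-H (1.07 ± 0.09), which are near-identical copies whose probes cannot be assigned to 1 gene with certainty. ANXA13, an intestinal annexin, fell by 1.43 ± 0.22, KLHL24 fell by 1.28 ± 0.08 and HNMT, which methylates histamine, fell by 1.11 ± 0.10. RGCC, a regulator of the cell cycle, fell by 1.07 ± 0.14, and PCK1, a rate-limiting enzyme of gluconeogenesis, fell by 1.03 ± 0.16. YPEL3 fell by 1.03 ± 0.07, QPRT, an enzyme of NAD synthesis, fell by 0.97 ± 0.08, and the insulin receptor adaptor IRS2 fell by 0.97 ± 0.08. TPPP3 fell by 0.93 ± 0.19 and MAP2K6, a kinase that activates p38, fell by 0.91 ± 0.06. The size for TPPP3 rests on COLO205 with fluid 1 (-2.13, against -0.66 to -0.36 in the other pairs). The fall of MAP2K6 rests on SNU-C1 (-1.72 and -1.67 with fluids 1 and 2, against -0.04 and -0.21 in COLO205). QPRT also fell more in SNU-C1 (-1.65 and -1.34) than in COLO205 (-0.64 and -0.26), as did TMT1A (-2.63 and -1.88 against -0.83 and -0.54). By the rule for naming genes, all of these large rises and falls had the same sign in 4 of 4 pairs. Their adjusted p lay between 6.0e-05 and 0.0276. Of the genes fixed in advance, STAT3, the transcription factor downstream of interleukin 6, rose by 0.33 ± 0.07 (adjusted p = 0.0104) and its target SOCS3 by 0.38 ± 0.09 (adjusted p = 0.0156). The lipid droplet protein gene PLIN2 rose by 0.69 ± 0.16 (adjusted p = 0.0163), ANGPTL4, which inhibits lipoprotein lipase, by 0.48 ± 0.09 (adjusted p = 0.00741), and the proliferation marker MKI67 by 0.25 ± 0.07 (adjusted p = 0.0302, higher in 3 of 4 pairs). The glucocorticoid target FKBP5 changed by 0.12 ± 0.07 and did not pass (adjusted p = 0.205, higher in 4 of 4 pairs). Between 1218 and 2091 genes passed when 1 array was left out, with over 1.5 times fewer without COLO205 at 0.1% (1346) or 5% (1564) with fluid 1, without SNU-C1 at 0.1% (1218) or 5% (1417) with fluid 1, and without SNU-C1 at 0.1% with fluid 2 (1600). Of 31 named calls, 23 held in all 8 of these fits, while SPRR1B, CEACAM6, SPRR1A, MT2A, HMOX1, SOCS3, PLIN2 and MKI67 were lost in at least 2, the omission of any 1 array ended at least 1 of these calls, and their adjusted p reached at most 0.117.

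By camera p, though not by mean change, lists of genes that rose with the dose were led by those of proliferation. Of 31 genes of G2 and mitosis, 23 rose and none fell, or 26 and 1 adjusted over the list alone, with a mean of 0.31. Examples were the kinesin gene KIF23 (0.54 ± 0.05), the mitotic kinases AURKA (0.56 ± 0.07) and PLK1 (0.52 ± 0.06) and CDC20 (0.53 ± 0.07). Of 29 genes of S phase and DNA replication, 23 rose, 25 adjusted over the list alone, with a mean of 0.31. They included the replication factors CLSPN (0.54 ± 0.06), GINS1 (0.45 ± 0.06) and CDC6 (0.55 ± 0.08) and the cyclin CCNE1 (0.53 ± 0.07). This rise was larger in SNU-C1, where the mean of the list was 0.62 and 0.47 with fluids 1 and 2 against 0.14 and 0.01 in COLO205. In COLO205 alone the list did not pass and none of its genes did with limma, also adjusted over the list alone (adjusted camera p = 0.173; adjusted p = 0.814 with an estimated correlation). Of 23 genes of MYC targets and ribosome biogenesis, 15 rose and 1 fell, or 19 and 1 adjusted over the list alone, with a mean of 0.29. LYAR (0.58 ± 0.07), MRTO4 (0.45 ± 0.06), the spermidine synthase SRM (0.51 ± 0.07) and the ornithine decarboxylase ODC1 (0.48 ± 0.07) rose, whereas MYC itself fell by 0.28 ± 0.06. Of 9 heat shock genes 7 rose, 8 adjusted over the list alone, such as HSPA4L (0.49 ± 0.06) and STIP1 (0.42 ± 0.06). All 5 metallothionein and zinc genes rose, also adjusted over the list alone, with a mean of 1.04. That mean was 1.53 and 1.49 in COLO205 and 1.31 in SNU-C1 with fluid 1, but -0.18 in SNU-C1 with fluid 2. In SNU-C1 the signal of MT1G at 0.1% (3.705) and of MT1F at 0.1% and 5% (4.28 and 4.27) lay under the filter level. The means in SNU-C1 are therefore uncertain in size. MT1G (2.12 ± 0.37) and MT1X (1.11 ± 0.12) led it, and metallothionein genes are close copies, so their separate values are uncertain. Of 10 NRF2 targets, which act against oxidative stress, 5 rose, 6 adjusted over the list alone, among them SRXN1 (0.59 ± 0.13) and TXNRD1 (0.41 ± 0.09). Of 8 genes of the mesenchymal state and matrix 4 rose, also 4 adjusted over the list alone. These were TNC, fibronectin (FN1, 0.78 ± 0.11), S100A4 (0.37 ± 0.09) and SNAI2 (0.31 ± 0.10). With camera this list passed in SNU-C1 but not in COLO205. TNC rose mainly in COLO205. FN1 rose by 0.99 and 1.44 in SNU-C1 with fluids 1 and 2, against 0.23 and 0.46 in COLO205. The adjusted camera p of these 7 lists was 3.85e-11 for G2 and mitosis, 2.24e-09 for S phase, 2.06e-07 for MYC targets, 1.35e-04 for heat shock, 0.00383 for metallothioneins, 0.00812 for NRF2 targets and 0.00936 for the matrix list. None kept its call with an estimated correlation between genes, where it was adjusted p = 0.733 with an estimated correlation for NRF2 targets and adjusted p = 0.575 with an estimated correlation for each of the others. The NRF2 call was also lost without COLO205 at 5% with fluid 1 (adjusted p = 0.0778).

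Lists that fell with the dose were those of Wnt targets, of cholesterol and fatty acid synthesis and of cytosolic ribosomal proteins. Of 19 Wnt target and intestinal stem cell genes 14 fell and none rose, or 14 and 1 adjusted over the list alone, with a mean of -0.32 (adjusted camera p = 2.06e-07; adjusted p = 0.322 with an estimated correlation). NKD1, a negative feedback gene of the pathway, fell by 0.65 ± 0.06 and LGR5, a marker of intestinal stem cells, fell by 0.67 ± 0.11. PROX1 fell by 0.53 ± 0.07 and CEMIP fell by 0.49 ± 0.07. Of 19 cholesterol synthesis genes 13 fell, 14 adjusted over the list alone, with a mean of -0.31 (adjusted camera p = 4.66e-07; adjusted p = 0.575 with an estimated correlation). SREBF2, the transcription factor of the pathway, fell by 0.54 ± 0.07, STARD4 fell by 0.56 ± 0.07 and HSD17B7 fell by 0.65 ± 0.09. The HMG-CoA synthase HMGCS1 fell by 0.51 ± 0.09 (adjusted p = 0.00602, lower in 4 of 4 pairs) and the sterol sensor INSIG1 fell by 0.53 ± 0.07 (adjusted p = 0.00332, lower in 4 of 4 pairs). Of 13 fatty acid synthesis genes 6 fell, also 6 adjusted over the list alone, with a mean of -0.24 (adjusted camera p = 0.00936; adjusted p = 0.575 with an estimated correlation). These included the desaturase SCD, which fell by 0.50 ± 0.06, the transcription factor MLXIPL, which fell by 0.79 ± 0.10, and ACSS2, which fell by 0.47 ± 0.06. Of 21 cytosolic ribosomal protein genes 4 fell, 3 adjusted over the list alone, with a mean of -0.11 (adjusted camera p = 0.00390; adjusted p = 0.575 with an estimated correlation). RPL10A fell by 0.22 ± 0.06 and RPS28 fell by 0.22 ± 0.06. The other 25 of 36 lists did not pass. Of 16 genes of the IL6-STAT3 response, 3 rose and none fell, also adjusted over the list alone (mean 0.12, adjusted camera p = 0.176; adjusted p = 0.821 with an estimated correlation). Of 13 genes of NF-kB and inflammatory cytokines 1 rose and 3 fell, also adjusted over the list alone (mean -0.12, adjusted camera p = 0.0859; adjusted p = 0.575 with an estimated correlation; 0.0385 with fry), with the chemokine CCL20 falling most, at -0.86 ± 0.08.

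**Figure D1:**
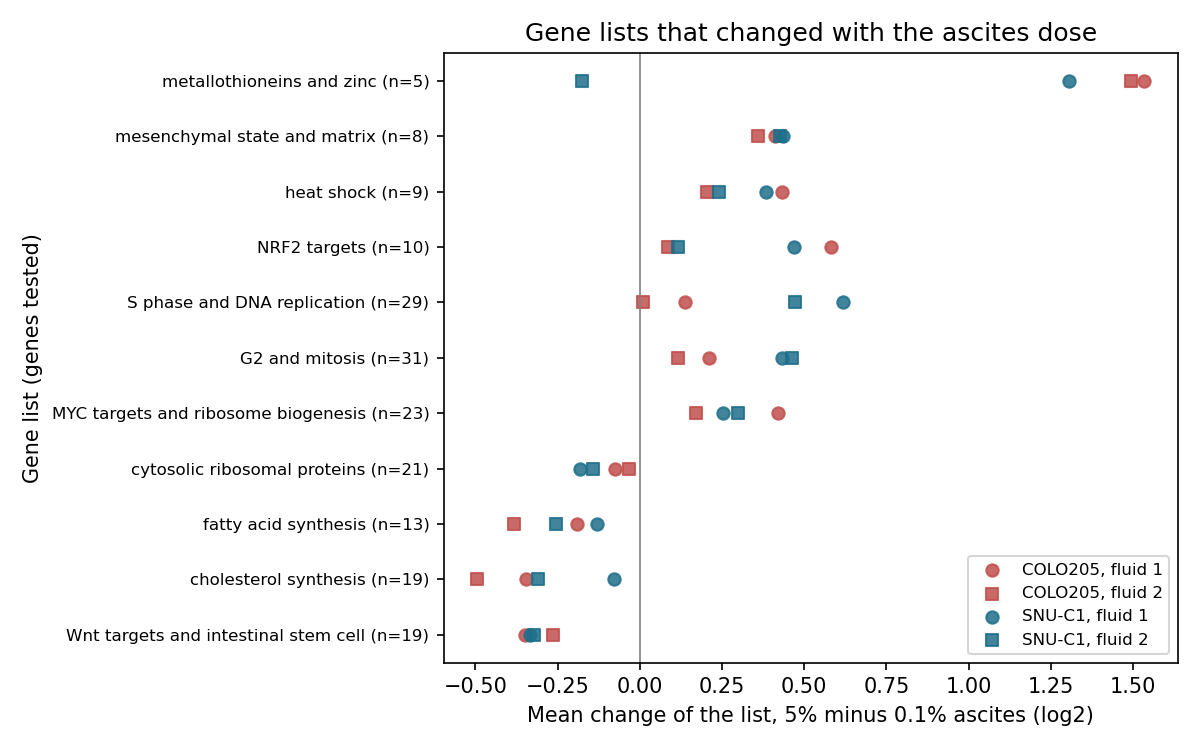
Mean change in log2 signal from 0.1% to 5% ascites of the 11 gene lists past the threshold, with 1 point for each of the 4 line and fluid pairs and the genes tested per list in brackets. All points of a list lie on the same side of 0, except that metallothioneins lay at -0.18 in SNU-C1 with fluid 2.

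In COLO205, TNC rose by 2.60 ± 0.17 (n = 2 pairs of arrays, adjusted p = 0.00125) and the metallothioneins MT1G and MT1X rose by 2.96 ± 0.52 (adjusted p = 0.0289) and 1.94 ± 0.17 (adjusted p = 0.00356). The growth factor-induced transcription factor EGR1 fell by 1.28 ± 0.14 (adjusted p = 0.00571) and CCL20, which attracts lymphocytes and dendritic cells, fell by 1.15 ± 0.11 (adjusted p = 0.00449). Of 10419 genes 454 passed, 154 higher and 300 lower at 5%, and 26 of them moved at least 2-fold, 12 up and 14 down. MIR4521 rose by 1.93 ± 0.14, MT1F by 1.42 ± 0.31 and SPRR3 by 1.38 ± 0.22. PCP4, a calmodulin regulator, rose by 1.35 ± 0.25 and the carbonic anhydrase CA12 by 1.03 ± 0.16. The noncoding RNA genes SNAR-B1 (1.85 ± 0.13), SNAR-C1 (1.54 ± 0.12), SNAR-H (1.06 ± 0.12) and SNAR-D (1.03 ± 0.19) rose together. KLHL24 fell by 1.502 ± 0.11, YPEL3 fell by 1.44 ± 0.10, TPPP3 fell by 1.40 ± 0.27 and ANXA13 fell by 1.35 ± 0.31. With fluids 1 and 2 TPPP3 was at -2.13 and -0.66 and ANXA13 at -1.95 and -0.75. PCK1 fell by 1.28 ± 0.23, the eosinophil chemokine CCL24 fell by 1.19 ± 0.18, MIR3189 fell by 1.17 ± 0.12 and RGCC fell by 1.09 ± 0.20. The matrix protein SMOC2 fell by 1.08 ± 0.21 and the noncoding RNA LINC00426 fell by 1.04 ± 0.18. HMGCS1 fell by 0.66 ± 0.12 (adjusted p = 0.0339) and INSIG1 fell by 0.58 ± 0.11 (adjusted p = 0.0307). The values of STAT3 (0.33 ± 0.09), SOCS3 (0.40 ± 0.12), PLIN2 (0.50 ± 0.22), ANGPTL4 (0.37 ± 0.12), FKBP5 (0.13 ± 0.09) and MKI67 (0.05 ± 0.10) did not pass, with adjusted p between 0.0909 and 0.791 and positive signs in 2 of 2 pairs, except 1 of 2 for MKI67. With each line and fluid pair as a block 255 genes passed, and with 1 array left out 12 or 7 passed without COLO205 at 0.1% or 5% with fluid 1, 69 or 244 without COLO205 at 0.1% or 5% with fluid 2, and 260 or 214 without either SNU-C1 array at 0.1% or 5%. Of 26 named calls only TNC, MIR4521, SNAR-B1, KLHL24 and YPEL3 held in all 8 of these fits, and the adjusted p of the others reached at most 0.284.

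By camera p, though not by mean change, gene lists in COLO205 were led by sterol synthesis. Of 19 cholesterol synthesis genes 9 fell, 14 adjusted over the list alone, with a mean of -0.42 (adjusted camera p = 3.88e-10; adjusted p = 0.531 with an estimated correlation). STARD4 fell by 0.84 ± 0.09, SREBF2 fell by 0.73 ± 0.10, SQLE, the epoxidase of the pathway, fell by 0.72 ± 0.11 and MSMO1 fell by 0.74 ± 0.12. Of 23 MYC target and ribosome biogenesis genes 8 rose and 1 fell, or 15 and 1 adjusted over the list alone, with a mean of 0.30 (adjusted camera p = 8.28e-08; adjusted p = 0.531 with an estimated correlation). Of 19 Wnt target genes 8 fell, 9 adjusted over the list alone, with a mean of -0.31 (adjusted camera p = 2.91e-05; adjusted p = 0.443 with an estimated correlation), among them PROX1, which fell by 0.76 ± 0.10, and LEF1, a transcription factor of the pathway, which fell by 0.57 ± 0.08. Of 19 genes of ERK feedback 7 fell and 1 rose, or 10 and 1 adjusted over the list alone, with a mean of -0.27 (adjusted camera p = 1.69e-04; adjusted p = 0.443 with an estimated correlation). Besides EGR1, ETV5 fell by 0.55 ± 0.08, the receptor EPHA4 fell by 0.63 ± 0.12 and IER3 fell by 0.40 ± 0.08. Of 20 serum and immediate early genes 5 fell, 6 adjusted over the list alone (mean -0.22, adjusted camera p = 0.00220; adjusted p = 0.531 with an estimated correlation), including KLF2, which fell by 0.68 ± 0.13. Heat shock genes (4 of 9 rose, 7 adjusted over the list alone, mean 0.32), G2 and mitosis (4 of 31 rose, or 8 with 1 lower adjusted over the list alone, mean 0.16) and metallothioneins (3 of 5 rose, 5 adjusted over the list alone, mean 1.51) each had an adjusted camera p of 1.29e-04, and adjusted p = 0.531 with an estimated correlation. Of 13 fatty acid synthesis genes 3 fell, 6 adjusted over the list alone (mean -0.29, adjusted camera p = 9.07e-04; adjusted p = 0.531 with an estimated correlation). NRF2 targets passed as a list with no single gene past the threshold and 3 of 10 higher adjusted over the list alone (mean 0.33, adjusted camera p = 0.00221; adjusted p = 0.556 with an estimated correlation). Autophagy and lysosome genes passed with no single gene past the threshold and 2 of 18 lower adjusted over the list alone (mean -0.12, adjusted camera p = 0.0202; adjusted p = 0.552 with an estimated correlation). Leaving out 1 array ended the list calls of NRF2 targets, of serum genes and of autophagy genes. The mean of NRF2 targets was 0.15 and 0.19 without COLO205 at 0.1% and at 5% with fluid 1. That of serum genes was -0.15 without COLO205 at 5% with fluid 1. That of autophagy genes was -0.06 and -0.10 without COLO205 at 0.1% and at 5% with fluid 2.

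In SNU-C1, CD38 fell by 2.76 ± 0.09 (n = 2 pairs of arrays, adjusted p = 5.82e-06) and ATOH1, the transcription factor of the intestinal secretory lineage, fell by 1.505 ± 0.16 (adjusted p = 0.00298). FN1 rose by 1.22 ± 0.16 (adjusted p = 0.00390), EMP1, a membrane protein induced by growth factors, rose by 1.11 ± 0.11 (adjusted p = 0.00255) and KITLG, the ligand of the KIT receptor, rose by 1.11 ± 0.12 (adjusted p = 0.00290). Of 10419 genes 1872 passed, 774 higher and 1098 lower at 5%, and 36 of them moved at least 2-fold, 9 up and 27 down. The membrane protein STEAP1 rose by 1.27 ± 0.29, SPRR1A by 1.25 ± 0.31, MIR4521 by 1.22 ± 0.14 and GPAT3 by 1.104 ± 0.20. HMOX1 rose by 1.08 ± 0.28, SNAR-H by 1.07 ± 0.12, KBTBD8 by 0.99 ± 0.10, the serine protease KLK7 by 0.99 ± 0.12 and SPRR3 by 0.98 ± 0.22. TMT1A fell by 2.25 ± 0.16, ELAPOR1 fell by 1.90 ± 0.25, MAP2K6 fell by 1.69 ± 0.08 and the stress-induced SESN3 fell by 1.52 ± 0.19. ANXA13 fell by 1.51 ± 0.31, QPRT fell by 1.49 ± 0.12, LINC00674 fell by 1.33 ± 0.21 and the peptidase MME fell by 1.24 ± 0.09. The cadherin-related gene CDHR1 fell by 1.19 ± 0.08 and HNMT fell by 1.18 ± 0.15. INSIG1 fell by 0.47 ± 0.11 (adjusted p = 0.0201), STAT3 rose by 0.34 ± 0.09 (adjusted p = 0.0412), PLIN2 by 0.88 ± 0.22 (adjusted p = 0.0308), ANGPTL4 by 0.59 ± 0.12 (adjusted p = 0.0151) and MKI67 by 0.45 ± 0.10 (adjusted p = 0.0168), each in 2 of 2 pairs. SOCS3 (0.36 ± 0.12), HMGCS1 (-0.36 ± 0.12) and FKBP5 (0.11 ± 0.09) did not pass, with adjusted p of 0.0747, 0.0779 and 0.436. Without SNU-C1 at 0.1% or 5% with fluid 1 249 or 287 genes passed, and without SNU-C1 at 0.1% or 5% with fluid 2 607 or 867 passed. Of 29 named calls 17 held in all 8 fits without 1 array, while those of STEAP1, SPRR1A, GPAT3, HMOX1, SPRR3, ANXA13, LINC00674, INSIG1, STAT3, PLIN2, ANGPTL4 and MKI67 were each lost without at least 1 SNU-C1 array, STAT3 also without either COLO205 array at 0.1%, with adjusted p of at most 0.259.

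Gene lists in SNU-C1 were led by the cell cycle. Of 31 genes of G2 and mitosis 23 rose, 28 adjusted over the list alone, with a mean of 0.45 (adjusted camera p = 1.61e-14; adjusted p = 0.552 with an estimated correlation). KIF23 rose by 0.71 ± 0.08, CDK1, the kinase of mitotic entry, by 0.64 ± 0.08, CCNA2 by 0.64 ± 0.08 and the checkpoint gene MAD2L1 by 0.66 ± 0.08. Of 29 genes of S phase and DNA replication 24 rose, 27 adjusted over the list alone, with a mean of 0.55 (adjusted camera p = 1.79e-14; adjusted p = 0.686 with an estimated correlation). CCNE2 rose by 0.93 ± 0.11, CCNE1 by 0.88 ± 0.11, CDC6 by 0.92 ± 0.12 and CLSPN by 0.86 ± 0.08. Of 23 MYC target and ribosome biogenesis genes 8 rose, 13 adjusted over the list alone, with a mean of 0.28 (adjusted camera p = 3.25e-05; adjusted p = 0.686 with an estimated correlation). Of 19 Wnt target genes 8 fell, 12 adjusted over the list alone, with a mean of -0.33 (adjusted camera p = 4.12e-05; adjusted p = 0.552 with an estimated correlation). PROM1, a stem cell surface marker, fell by 1.003 ± 0.13, APCDD1, an inhibitor of the pathway, fell by 0.78 ± 0.10, NKD1 fell by 0.75 ± 0.09 and AXIN2 fell by 0.57 ± 0.09. Of 8 mesenchymal state and matrix genes 3 rose, 5 adjusted over the list alone, which by value were led by FN1 and S100A4 at 0.67 ± 0.12 (list mean 0.43, adjusted camera p = 0.00755; adjusted p = 0.552 with an estimated correlation). Of 9 heat shock genes 5 rose, also 5 adjusted over the list alone (mean 0.31, adjusted camera p = 0.00171; adjusted p = 0.686 with an estimated correlation). Of 21 cytosolic ribosomal protein genes 2 fell and none passed adjusted over the list alone (mean -0.16, adjusted camera p = 0.00132; adjusted p = 0.686 with an estimated correlation). Of 19 cholesterol synthesis genes 4 fell, also 4 adjusted over the list alone (mean -0.19, adjusted camera p = 0.0101; adjusted p = 0.750 with an estimated correlation). Of 16 genes of the IL6-STAT3 response 1, STAT3, rose and none passed adjusted over the list alone (mean 0.19, adjusted camera p = 0.0419; adjusted p = 0.750 with an estimated correlation). The cholesterol call was lost without SNU-C1 at 0.1% (adjusted p = 0.155) or 5% (0.130) with fluid 2, and the IL6-STAT3 call without SNU-C1 at 0.1% (0.112) or 5% (0.378) with fluid 1 and when arrays were centred on their median (0.0521).

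**Figure D2:**
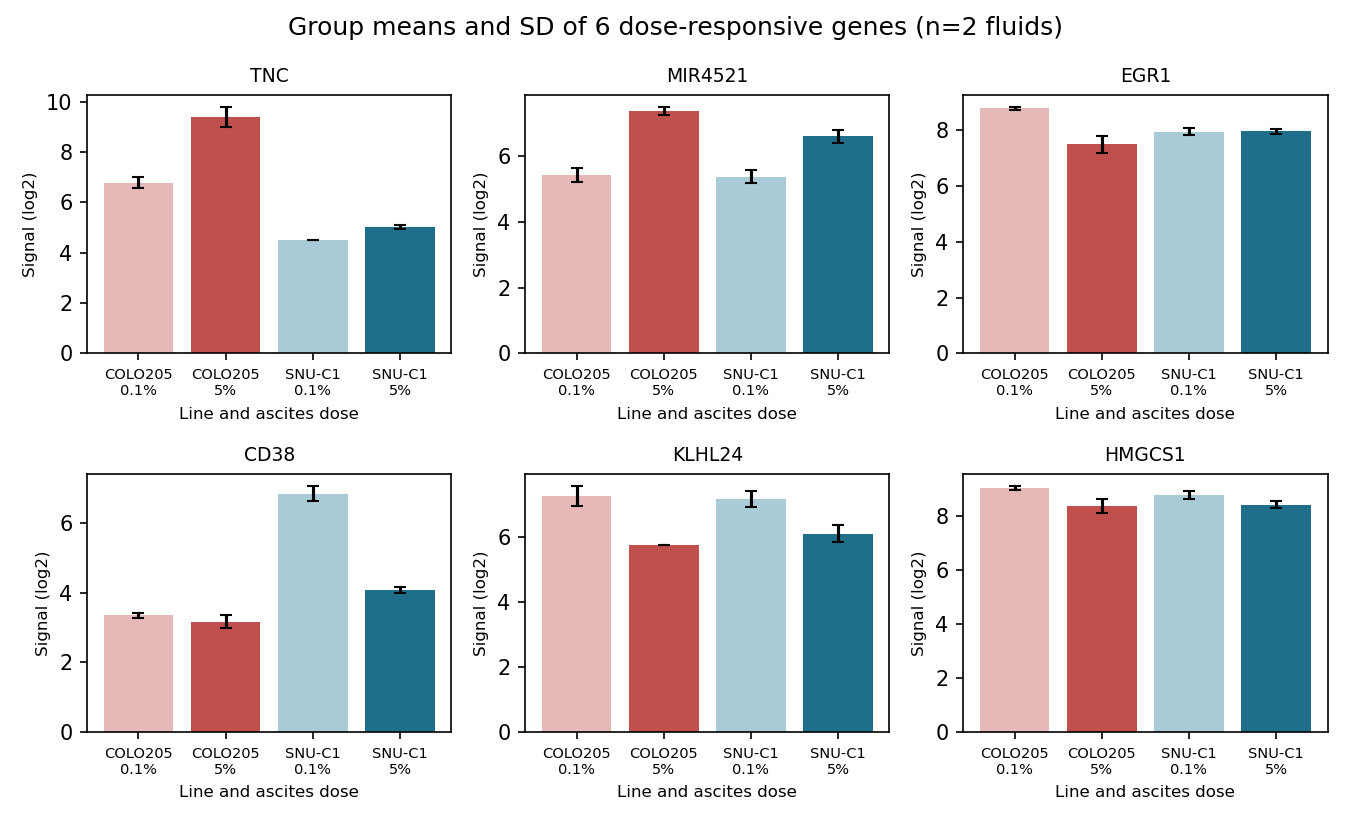
Group mean signal in log2 units of 6 genes, with bars for the mean and error lines for the SD of the 2 arrays of a group (n = 2 fluids). The mean of TNC goes from 6.79 to 9.39 in COLO205 and from 4.51 to 5.03 in SNU-C1.

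The lines were compared in how they responded, as the dose effect in COLO205 minus that in SNU-C1. CD38 differed by 2.57 ± 0.12 (n = 2 pairs per line, adjusted p = 0.000181). Its signal in COLO205 was 3.35 at 0.1% and 3.17 at 5%, under the filter level, so a fall could not be seen there and the value does not measure a difference of responses. TNC rose more in COLO205 by 2.08 ± 0.24 (adjusted p = 0.0363) and MT1X by 1.67 ± 0.25 (adjusted p = 0.0480). MAP2K6 (1.57 ± 0.12, adjusted p = 0.00314) and ATOH1 (1.79 ± 0.23, adjusted p = 0.0480) fell in SNU-C1. In COLO205 ATOH1 was at 0.16 and 0.41 with fluids 1 and 2 and did not pass. EGR1, the EGF receptor ligand HBEGF and the kinase SGK1 had a lower effect in COLO205, with differences of -1.29 ± 0.19, -1.39 ± 0.21 and -1.05 ± 0.15 (adjusted p = 0.0480 for EGR1 and SGK1, 0.0481 for HBEGF), as had ZNF165 (-1.02 ± 0.14, adjusted p = 0.0480). The signal of SGK1 in SNU-C1 at 0.1% was under the filter level, so its rise there is uncertain in size. The matrix gene MXRA5 was at -1.36 ± 0.19 (adjusted p = 0.0480), but its signal in COLO205 was 4.22 and 3.78 at 0.1% and 5%, both under the filter level, so this value does not measure a difference of responses either. By the rule for naming genes, each difference had 1 sign in both fluids. Of 10419 genes 28 passed, 19 higher and 9 lower in COLO205. Across genes the effects in the lines correlated at a Pearson r of 0.518 and a Spearman rho of 0.511 over 10419 genes, which are not independent replicates. Of the genes called in each line, 76 rose in both where independent lists of these lengths would share 11.4, 172 fell in both against 31.6, and 5 were called in opposite directions against 38.5. The calls in both lines used the same variance estimate per gene. The lists are therefore not independent, and the overlap without a shared response may exceed these figures. Of 29 S phase genes none passed singly, but 23 were lower in COLO205 adjusted over the list alone, with a mean difference of -0.47 (adjusted camera p = 9.48e-17; adjusted p = 0.648 with an estimated correlation). The list of G2 and mitosis differed by -0.28, with 8 of 31 lower adjusted over the list alone and none past the threshold over all genes (adjusted camera p = 4.44e-11; adjusted p = 0.648 with an estimated correlation). Of 19 genes of ERK feedback 2 were lower, EGR1 and HBEGF, and 10 adjusted over the list alone, with a mean difference of -0.46 (adjusted camera p = 4.36e-09; adjusted p = 0.285 with an estimated correlation; 0.0161 with fry). Another 6 lists passed with camera, with mean differences between -0.33 and 0.95. None of them passed with an estimated correlation, and the calls of 4 were lost without 1 array. With each line and fluid pair as a block 4 genes passed, and with 1 array left out 2 or 1 passed without COLO205 at 0.1% or 5% with fluid 1, 6 or 4 without SNU-C1 at 0.1% or 5% with fluid 1, 8 or 18 without COLO205 at 0.1% or 5% with fluid 2, and 4 or 10 without SNU-C1 at 0.1% or 5% with fluid 2. Of the 10 named differences only that of CD38 held in every fit, that of MAP2K6 was lost without COLO205 at 5% with fluid 1 (1.53, adjusted p = 0.0556), and the others were lost without at least 6 of the 8 arrays, with adjusted p of at most 0.207.

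**Figure D3:**
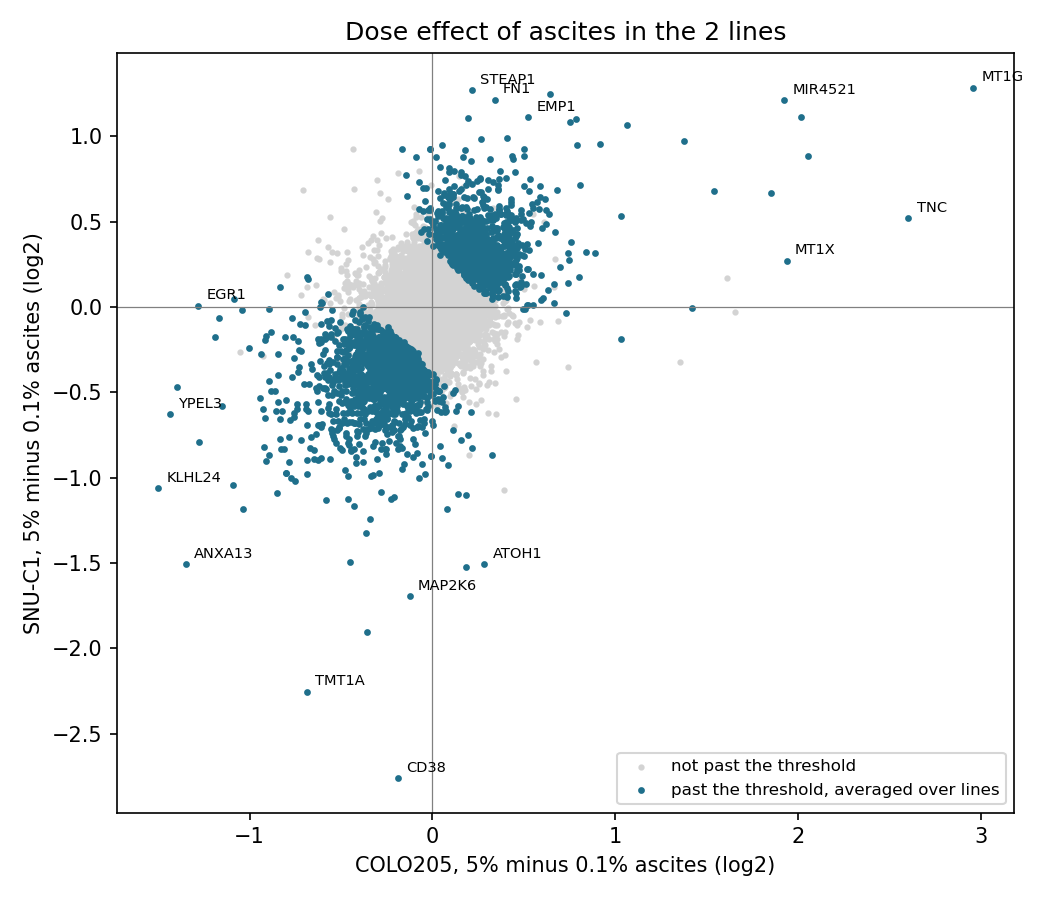
Change in log2 signal from 0.1% to 5% ascites in COLO205 (horizontal) and SNU-C1 (vertical), with 1 point for each gene drawn. Any Y-linked and other sex-specific genes were not drawn. The effects correlated at r = 0.518 across all 10419 genes tested, with TNC, MT1X and CD38 among the genes away from the diagonal.

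The lines themselves were compared over both doses and fluids, as COLO205 minus SNU-C1. PIWIL1, a germline PIWI protein, was measured 6.74 ± 0.06 log2 units higher in COLO205 (n = 4 pairs of arrays, adjusted p = 2.62e-10), while PTGS2, the inducible cyclooxygenase, was at -6.74 ± 0.16 (adjusted p = 8.54e-09). The signal of PIWIL1 in SNU-C1 and of PTGS2 in COLO205 lay under the filter level. So did at least 1 group mean of 15 of the 24 genes named for this comparison, whose differences are lower bounds. Differences were -5.23 ± 0.09 for the keratin KRT20, -5.08 ± 0.10 for the guanylyl cyclase receptor GUCY2C, -5.25 ± 0.36 for CEACAM6 and -4.78 ± 0.35 for CEACAM5. Of 10419 genes 6531 passed, 3362 higher and 3169 lower in COLO205, and 1097 of them by at least 2-fold, 614 higher and 483 lower. Also higher in COLO205 were AFAP1-AS1 (5.68 ± 0.09), the bile acid conjugating enzyme BAAT (5.61 ± 0.16), FEM1C (5.46 ± 0.06), CD109 (5.46 ± 0.06), LPXN (5.15 ± 0.09), the leukosialin gene SPN (5.04 ± 0.07) and TRERF1 (5.02 ± 0.06). ASB4 (4.98 ± 0.09), CHST11 (4.90 ± 0.06), the hormone FGF19 (4.84 ± 0.12) and the pseudogene CEP192P1 (4.79 ± 0.10) followed. Lower in COLO205 were SCEL (-5.68 ± 0.20), HLTF (-5.49 ± 0.08), MME (-5.44 ± 0.06), TMEM47 (-5.14 ± 0.09), PLBD1 (-4.90 ± 0.09), EPHA7 (-4.77 ± 0.13) and the interferon-induced IFITM1 (-4.64 ± 0.08). By the rule for naming genes, these 24 had 1 sign in 4 of 4 pairs. Their adjusted p was at most 4.79e-06, and every call held in all fits without 1 array. Of 20 genes of enterocyte differentiation 12 were lower and 2 higher, also adjusted over the list alone, with a mean of -1.32 (adjusted camera p = 0.0104; adjusted p = 0.878 with an estimated correlation). Of 27 genes of epithelial junctions and keratins 17 were lower and 4 higher, also adjusted over the list alone, with a mean of -0.65 (adjusted camera p = 0.0170; adjusted p = 0.878 with an estimated correlation). Of 18 genes of the type I interferon response 14 were higher and 3 lower, also adjusted over the list alone, with a mean of 0.92 (adjusted camera p = 0.00382; adjusted p = 0.878 with an estimated correlation), as in the tetherin gene BST2 (3.94 ± 0.07) and SAMD9L (3.43 ± 0.11). Of 31 genes of G2 and mitosis 23 were higher and 1 lower, 25 and 1 adjusted over the list alone (mean 0.51, adjusted camera p = 2.2e-05; adjusted p = 0.878 with an estimated correlation). Of 29 S phase genes 22 were higher and 4 lower, 23 and 4 adjusted over the list alone (mean 0.55, adjusted camera p = 1.40e-04; adjusted p = 0.957 with an estimated correlation). Of 10 genes of the unfolded protein response 8 were higher and 1 lower, also adjusted over the list alone (mean 0.53, adjusted camera p = 0.0125; adjusted p = 0.878 with an estimated correlation).

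The fluids were compared as fluid 2 minus fluid 1 over both lines and doses, a difference that cannot be told apart from any batch in which the arrays of a fluid were made. No gene passed with limma, while 922 had an unadjusted p under 0.05, and the smallest adjusted p was 0.503. The genes with the smallest p and 1 sign in all 4 pairs were ZNF224 at -0.40 ± 0.06, ZNF439 at 0.35 ± 0.06, the acetyltransferase gene SAT2 at -0.31 ± 0.06 and TCP11L2 at -0.32 ± 0.06, each with an adjusted p of 0.503. With camera 13 of 36 lists passed, none of them with a single gene past the threshold over all genes. Only 3 passed when SNU-C1 at 5% with fluid 1 or with fluid 2 was left out. The calls of 3 lists, S phase, G2 and mitosis and PPAR, held without any 1 array. S phase genes were higher with fluid 2 by a mean of 0.18 and genes of G2 and mitosis by 0.13, while PPAR and fatty acid oxidation genes had a mean of -0.21. In SNU-C1 at 5% S phase genes were not higher with fluid 2. Relative to their mean over all arrays they were at 0.002 with fluid 1 and -0.008 with fluid 2. At 0.1% they were at -0.61 and -0.48 in SNU-C1 and at 0.06 and 0.42 in COLO205 with fluids 1 and 2. In COLO205 at 5% they were at 0.20 and 0.43. The gap between fluids in S phase genes was thus wider at 0.1% than at 5% in both lines. For G2 and mitosis it was wider at 0.1% in COLO205 but not in SNU-C1. All 13 lists were at adjusted p = 0.626 with an estimated correlation or above, and none passed with fry.

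Whether the dose effect differed between the fluids was tested only after the other results had been seen. No gene passed with limma, 375 had an unadjusted p under 0.05 and the smallest adjusted p was 0.837. The genes with the smallest p were taken among those with 1 sign in both lines. As the effect with fluid 2 minus that with fluid 1, KYNU, an enzyme of tryptophan breakdown, was at -1.24 ± 0.16 and HMOX1 at -1.09 ± 0.19. The reductase PTGR1 was at -0.75 ± 0.14, SRXN1 at -0.66 ± 0.13 and ANXA13 at 1.14 ± 0.20. The adjusted p of these genes lay between 0.837 and 0.999. Of 36 lists 13 passed with camera, all with a lower effect of fluid 2, and none with an estimated correlation or with fry. Leaving out 1 array ended 12 of the 13 calls, and 6 lists passed without SNU-C1 at 5% with fluid 1 and 5 without COLO205 at 0.1% with fluid 2. The call that held was that of NRF2 targets, at an adjusted camera p of at most 9.85e-06. The mean difference was -0.42 for NRF2 targets, whose dose effect was 0.58 and 0.47 with fluid 1 and 0.09 and 0.12 with fluid 2 in COLO205 and SNU-C1 (adjusted camera p = 3.62e-09; adjusted p = 0.421 with an estimated correlation).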

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

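The patterns weighed here were picked from the results, the test of sterol uptake, the choice of splits and the comparison of dose effects between fluids were chosen only after the results had been seen, and what the other tests would show was written down before they were run. Dose effects that differ between the lines, dose effects of gene lists that differ between the lines or the fluids, and signal in probe rows outside the gene counts were singled out here.

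The difference of the dose effect between lines passed at 28 genes. As the effect in COLO205 minus that in SNU-C1 it was 2.57 for CD38, 2.08 for TNC, 1.79 for ATOH1, 1.67 for MT1X, 1.57 for MAP2K6, -1.39 for HBEGF, -1.36 for MXRA5, -1.29 for EGR1, -1.05 for SGK1 and -1.02 for ZNF165. The signals of CD38 and MXRA5 in COLO205 at both doses, and of SGK1 in SNU-C1 at 0.1%, lay under the filter level, so the values of CD38 and MXRA5 do not measure a difference of responses and that of SGK1 is uncertain in size. Gene lists that differed between the lines with camera were S phase (-0.47), ERK feedback (-0.46), serum and immediate early genes (-0.33), G2 and mitosis (-0.28), the unfolded protein response (-0.23), cholesterol synthesis (-0.23), autophagy and lysosome (-0.16), cytosolic ribosomal proteins (0.11) and metallothioneins (0.95). None of these 9 lists passed with an estimated correlation, and ERK feedback alone passed with fry. Between 0 and 2 genes of each list passed singly. In SNU-C1 the signal of MT1G at 0.1% and of MT1F at both doses lay under the filter level. The difference for metallothioneins is therefore uncertain in size. Leaving out 1 array ended the call for metallothioneins, whose mean difference was 0.84, 0.58 and 0.33 without COLO205 at 5%, SNU-C1 at 0.1% and SNU-C1 at 5% with fluid 2. That for cholesterol synthesis was ended without SNU-C1 at 5% with fluid 1 (mean -0.15). The call for autophagy was ended without SNU-C1 at 0.1% or 5% with fluid 1 (means -0.12 and -0.08) or COLO205 at 0.1% with fluid 2 (-0.10). That for ribosomal proteins was ended without SNU-C1 at 0.1% or 5% with fluid 1, COLO205 at 0.1% or 5% with fluid 2 or SNU-C1 at 0.1% with fluid 2. Its means in these fits were 0.09 to 0.12. It was also ended when arrays were scaled otherwise (adjusted p at most 0.0599).

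The dose effects of 13 lists were lower with fluid 2 than with fluid 1 with camera. The mean differences were -0.76 for metallothioneins, -0.42 for NRF2 targets, -0.24 for the IL6-STAT3 response, -0.23 for PPAR and fatty acid oxidation, -0.23 for glucocorticoid targets, -0.19 for cholesterol synthesis and -0.19 for heat shock. They were -0.18 for neuroendocrine genes, -0.18 for hypoxia and glycolysis, -0.16 for fatty acid synthesis, -0.14 for autophagy and lysosome, -0.12 for the type I interferon response and -0.10 for MYC targets and ribosome biogenesis. Leaving out 1 array ended 12 of these calls, all but that of NRF2 targets, and 6 lists passed without SNU-C1 at 5% with fluid 1 and 5 without COLO205 at 0.1% with fluid 2. Metallothioneins were at -0.08 (adjusted p = 0.861) without SNU-C1 at 5% with fluid 2. No gene passed for this difference with limma, while 375 had an unadjusted p under 0.05, and no list passed with an estimated correlation or with fry. The size for metallothioneins is uncertain, as in SNU-C1 MT1G at 0.1% and MT1F at both doses lay under the filter level. Fluids and any batch of the arrays cannot be told apart.

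Among 15462 probe rows unnamed here that passed the same filter, 1128 passed for the dose averaged over both lines, 289 higher and 839 lower at 5%. These probe rows enter no comparison of genes.

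Over 60 cell cycle genes the mean dose effect was 0.49 in SNU-C1 and 0.12 in COLO205, a mean difference of -0.37 (-0.3745). In COLO205 the S phase list did not pass, while that of G2 and mitosis passed with camera (mean 0.16), with 4 of 31 genes past the threshold. For the difference between lines neither list passed with an estimated correlation (adjusted p = 0.648). Since these genes were 0.72 log2 units higher in COLO205 at 0.1%, a compressed signal near the top of the range was weighed. Lists of random genes matched on that level and on the gap between the lines gave -0.142 to 0.00637 in their central 95%. So matched genes did not differ by as much. The random genes were drawn singly, and the pattern was picked for its size, so this range does not measure how unusual the pattern is. No single array accounts for the mean difference, as the value nearest to 0 in fits without 1 array was -0.308, with a range of -0.441 to -0.308. A faster division of COLO205 at 0.1% that leaves less room for a rise was not tested and stays open. A different growth response of the lines to ascites may account for the pattern, as a hypothesis.

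Cholesterol synthesis genes had a mean dose effect of -0.3075 over 19 genes averaged over the lines, -0.42 in COLO205 and -0.19 in SNU-C1. No call of this list passed with an estimated correlation (adjusted p = 0.575, 0.531 and 0.750 in that order). That in SNU-C1 was lost with camera without SNU-C1 at 0.1% or 5% with fluid 2, where the mean was -0.12 and -0.11. A drift shared by genes of that signal level is argued against only in that random lists matched on level gave -0.0918 to 0.109. The random genes were drawn singly, and the list was picked for its fall. So this range does not measure how unusual the mean of the list is. Uptake of sterols from the ascites may lower this pathway, and would raise targets of the sterol sensor LXR, but over 3 such targets outside the lipid synthesis lists the mean was -0.0125 with an interval over genes of -0.685 to 0.660, as MYLIP was at -0.28, LPCAT3 at 0.26 and APOE at -0.02. These genes are too few and too divided to decide, so sterol uptake cannot be told apart here from other routes to lower sterol synthesis.

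Other splits of the 8 arrays were compared in an additive model, with only those splits that part all 4 pairs of arrays alike in the other factors, as the real split does. There are 8 such splits for each factor, too few for a share under 0.05. The real split gave 1862 genes for the dose and 0 in the highest other (1 of 8 splits gave as many). It gave 6285 for the lines and 0 in the highest other (1 of 8). For the fluids it gave 0 and 0 in the highest other (8 of 8), where a count of 0 has nothing to compare. In the other splits for the dose and the lines, the real difference was left in the residual spread, which lowers their counts. The counts of these splits therefore do not show how unusual the real ones are.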

How the results depend on the processing

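Outside fits of single fluids or without 1 array, the count for the dose averaged over both lines ranged from 1862 to 3629 and that for the lines from 5426 to 7155, and that for the fluids was 0. Within fluid 1 alone the dose effect passed at 2 genes and the line difference at 3851, and within fluid 2 alone the dose effect passed at 84, in fits of 4 arrays with 1 residual degree of freedom. In COLO205 454 genes became 255 with a replicate block for each line and fluid pair, 892 with an intensity trend, 102 without a filter, 700 with the filter at the 50th percentile and 1018 at an adjusted p of 0.1. In SNU-C1 1872 became 1247 without a filter. The 28 differences between lines became 4 with that block, 155 with the trend, 4 without a filter, 55 at the 50th percentile, 6 with all probe rows tested separately, 5 with quantile normalization (5 higher and 0 lower, against 19 and 9) and 130 at an adjusted p of 0.1. The filters change how many genes are tested and the threshold is looser by construction, and the cause of the other shifts was not tested. Without the replicate block of the fluid 2402, 386, 1694, 23 and 6442 genes passed for the dose, COLO205, SNU-C1, the difference and the lines, and a block changed no other call on the counts. With 1 array left out the counts ranged from 1218 to 2091 for the dose, 7 to 260 in COLO205, 249 to 1872 in SNU-C1, 1 to 18 for the difference, 5916 to 6268 for the lines, 0 to 0 for the fluids and 0 to 1 for the dose by fluid, where the lone array of a group is assumed to vary like the others. Numbers of lists then ranged from 10 to 13, 10 to 12, 8 to 12, 7 to 11, 6 to 8, 3 to 16 and 5 to 14 in the same order. With an estimated correlation 0 lists passed in any of the 7 comparisons, against 11, 11, 9, 9, 6, 13 and 13. In the simulated data, with noise independent between genes, 1 list was shifted by 0.2 log2 units. Its adjusted camera p was 2.6e-29 with the preset and 0.034 with an estimated correlation. A list that fails with an estimated correlation is therefore not shown to be unchanged. With fry 10 lists passed for the dose averaged over both lines, 4 in COLO205, 5 in SNU-C1, 1 for the difference and 24 for the lines. It passed 0 for the fluids and 0 for the dose by fluid, while camera without a filter passed 7 for the dose by fluid. The correlation of the effects across genes, 0.518, was 0.443 and 0.397 within fluid 1 and fluid 2, 0.415 and 0.408 with fluids crossed between the lines, and 0.449 without a filter. MKI67 in COLO205 changed sign without COLO205 at 5% with fluid 1 (-0.0847, adjusted p = 0.694) and was 0.185 without COLO205 at 5% with fluid 2. Of the values of named genes under alternatives 2555 kept direction and side of the threshold, 298 lost the call and 6 gained it, and of those of lists 730 kept it and 233 lost it. No detection calls were used, so signal over background limits dim genes in an unknown way.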

Other observations

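The test of growth arrest genes was chosen only after the gene results had been seen. Of 585 long noncoding RNA genes tested 128 passed for the dose averaged over both lines, 21 higher and 107 lower at 5%, and the balance was 26 to 100 and 32 to 101 under 2 other scalings. Of 9184 protein coding genes 2289 passed, 1073 higher and 1216 lower, a balance that turned to 1269 and 1103 or 1263 and 1114 under those scalings. Of 376 microRNA genes 49 passed, 27 higher and 22 lower, led by MIR4521.

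Some lists held opposite movements and did not pass as lists with camera for the dose averaged over both lines (adjusted p between 0.283 and 0.969), though the goblet list passed with fry (adjusted p = 0.0385). Of 18 genes of the type I interferon list 3 rose and 3 fell, and of those that rose ISG15 was at 0.29 ± 0.06 and the tetherin gene BST2 at 0.33 ± 0.07, the latter at 0.60 ± 0.10 in COLO205 and 0.06 ± 0.10 in SNU-C1, where its signal was low. Of 21 genes of hypoxia and glycolysis 8 rose and 4 fell, and PGAM1 (0.62 ± 0.10), LDHA (0.39 ± 0.06) and GPI (0.29 ± 0.06) were among the 8. Of 27 epithelial genes 4 rose and 1 fell, with KRT20 (0.63 ± 0.09), CDS1 (0.55 ± 0.07) and PKP3 (0.35 ± 0.06) among the 4. Of 10 genes of the goblet list 2 rose, TFF1 (0.50 ± 0.06) and KLK6 (0.49 ± 0.07), and 1 fell. Of 12 p53 targets 2 rose and 3 fell, among these TP53INP1, which fell by 0.74 ± 0.08, and CCNG1, which fell by 0.37 ± 0.06. These members were chosen by the smallest p in the direction of each list, so genes that moved the other way are not named.

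Markers of cell types other than epithelium, written down as lists beforehand, had median levels between 3.95 and 5.07 log2 units. In a fit of all named genes without a filter 1 of 12 leukocyte, 0 of 15 mesothelial, 1 of 8 fibroblast, 0 of 4 erythrocyte and platelet, 0 of 9 endothelial and 3 of 14 hepatocyte genes passed for the dose. The brightest were lysozyme (LYZ, level 10.6), which intestinal epithelium also expresses and whose dose effect was -0.39, and TM4SF1 (level 10.5) at 0.12.

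Among the strongest falls with the dose were KLHL24, YPEL3 and IRS2, which led to a hypothesis that the transcription factors of the FOXO family, which insulin and growth factors switch off, may be less active at 5%. A list of 24 FOXO and starvation genes was written after the gene results were seen, and some of its members had been in view in other lists. Of 16 tested genes not named as large changes 13 fell past the threshold and 1, DEPP1 (0.20 ± 0.06), rose, with a mean of -0.35 (-0.3492), -0.36 in COLO205 and -0.34 in SNU-C1. Since the members were chosen with the gene results in view, this mean decides neither for lower FOXO activity nor against a drift of genes of that signal level, and both stay open. Examples were PNRC1, which fell by 0.66 ± 0.06, CCNG2, which fell by 0.66 ± 0.07, and INSR, the insulin receptor, which fell by 0.54 ± 0.07.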
